A study of Solanum lycopersicum with 3 samples.

How the data were processed

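Spatial transcriptome libraries of galls of Moneymaker tomato roots were analysed, 1 each from days 3, 5 and 7 after inoculation with Meloidogyne incognita. Per the labels' protocols, galls were embedded in OCT compound, frozen and cut into 15 µm sections, and libraries were sequenced on an Illumina NovaSeq instrument. The deposited matrices hold raw whole-number counts per gene model and spot, and the deposited position tables give x and y of each spot in a unit that is not stated. The spatial platform, aligner, counter, tissue detection, genome build and annotation are not given in the sources used here, and neither is whether a count is a read or a unique molecule. The word count is therefore used throughout. The number of tissue sections per library is not given either, and the word section stands for all spots of 1 library. All deposited spots were taken as lying over tissue, and no doublet caller was run because spots are small regions and not cells.

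All 3 matrices hold the same 35887 gene models. Neither their identifiers nor their model names matched the reference table of tomato genes (0 matches, by gene, locus tag, synonym or accession, assembly SLM_r2.1). No identifier lacked the tomato prefix, so no nematode transcripts could be separated. The 38 gene and marker lists fixed before the data were examined were to be matched on gene descriptions, and 0 listed genes matched. Shifts of gene lists between days and list levels by region were therefore not computed, and the clustering, which was to leave out listed genes, left out none.

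Spots with at least 200 detected genes were kept. This removed 0 spots at day 3, 141 of 3883 at day 5 (3.63%) and 2236 of 8067 at day 7 (27.7%, with 3.75% of the counts). Counts were summed over spots per section and scaled to CPM by the total of the section. For each pair of days the log2 ratio of CPM was computed with an exact conditional binomial 95% interval, which covers counting error only. It does not cover differences between plants, galls or libraries, and no p-value was computed because each day had 1 library and spots are not replicates. A gene was counted as higher or lower where the interval lay beyond 2-fold and the higher section had at least 50 CPM. A count of 0 allows a level of up to 3 counts, which corresponds to 0.302, 0.432 and 0.404 CPM at days 3, 5 and 7. Genes were to be named as the 12 with the highest and the 12 with the lowest ratio per pair of days, among genes with at least 100 counts and 50 CPM in the higher section, a descriptive name, and the same direction under other scaling and in comparisons of parts of the sections. As no gene model had a descriptive name, the first 2 per direction by the rest of the rule were named. Identifiers of regions, patchy genes and tissue positions were named as leading members of their lists.

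Spots lie on a hexagonal grid with a spacing of 6.69 file units. After the positions were seen, connected pieces of tissue were defined by linking neighbouring spots. The distance of each spot from the nearest empty grid site gave the distance from the edge, and the largest circle inside the tissue that covers a spot gave the local thickness. Spots of each piece were split into 3 zones of equal numbers of spots by either measure, and counts summed over the extreme zones were compared as log2 ratios of CPM with a pseudocount of 5, over 3953 genes with a mean of at least 50 CPM. The 4 pieces of day 7 touch the border of the measured area, where no edge was assumed. For groups of genes defined by position, the median log2 ratio between days was ranked among 10000 random lists of the same size matched on mean expression, as a description of these libraries.

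Regions were found per section by Leiden clustering at resolution 0.6 on a graph of 15 neighbours, from 20 principal components of log1p counts per 10000 of the 2000 most variable genes. Regions of different days were compared by the correlation across genes of their log2 ratios against the rest of their section. Moran's I was computed over the 6 nearest spots on counts thinned per spot to 337, the 10th percentile of counts per spot in the section where it was lowest, for genes with at least 100 counts left. Thinning left out 0 spots at day 3, 257 at day 5 and 576 at day 7.

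The steps were tested on simulated data. With 200 genes changed 3-fold among the 35887 and counts drawn at the real depths, the comparison of days called 97% to 100% of the changed genes in each direction and 0 of 35687 unchanged genes. The changed genes were taken from those with at least 50 CPM, while most unchanged ones lay below that minimum and could not be called. Both sections were drawn from 1 shared profile with counting error only. The 0 therefore says nothing about calls due to differences between pieces, galls or libraries. With 200 of 2000 genes raised 3-fold in the outer zone of day 7, 99.5% were recovered in every day 7 piece and 0 of 1800 unchanged genes were called. All spots were drawn from the mean profile of day 7 with counting error only. This 0 therefore says nothing about genes with other patterns in space. With 200 of 2000 genes raised 5-fold in 1 patch of day 7, 44 of the 198 that passed the count filter exceeded every unpatterned gene in Moran's I (22.2%), so low values of I do not show that a gene is even. Alternatives for scaling, spot filters, weighting of spots, parts of sections, clustering and neighbours were fixed before the data were examined, and those on pieces, depth, tissue position and region matches were added afterwards. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and leidenalg 0.10.2.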

Results

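Spatial transcriptomes were measured in galls of Moneymaker tomato roots infected with the root-knot nematode Meloidogyne incognita, a parasite whose juveniles induce enlarged multinucleate feeding cells (giant cells) inside the root. Galls were collected on days 3, 5 and 7 after inoculation with 5000 juveniles per plant, and 1 library from 15 µm tissue sections was analysed per day. The labels do not give the number of sections per library, and the word section stands here for all spots of 1 library. Uninfected roots were not analysed here. Each day was represented by 1 library, so no comparison between days had a replicate check, and each difference describes these 3 sections. The day 3 section held 1835 spots and 9936818 counts, with a median of 4865 counts and 2561 genes per spot. The day 5 section held 3742 spots with at least 200 detected genes, 6951588 counts and medians of 1099.5 counts and 784 genes. The day 7 section held 5831 such spots, 7421423 counts and medians of 826 counts and 622 genes. The spots formed 1 connected piece of tissue at day 3, 2 pieces at day 5 and 4 pieces at day 7. Most spots left out at day 7 came from piece 2, which kept 1233 of 2864. Its kept spots had a median of 556 counts, the lowest of all pieces. The labels do not say whether pieces are separate sections, separate galls or parts of one gall, so they were used only to show the spread within a library. Counts were assigned to 35887 gene models whose identifiers the files do not pair with gene names, and 0 of them matched the reference table of tomato genes. At most 2 identifiers per direction are therefore printed for each comparison, and differences are described mainly by tissue position and region.

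The comparison of day 5 with day 3 asked how transcript levels differed early in gall growth. At day 5, 484 genes were at least 2-fold higher and 295 at least 2-fold lower than at day 3, counting only genes with at least 50 CPM (counts scaled to the section total) in the higher section and a 95% counting interval beyond 2-fold. Solyc_MM_10G001532 stood at 0.201 CPM at day 3 (2 counts) and 1005 CPM at day 5, a ratio of 4992 with a counting interval of 1381 to 41231, and its level was 969 and 1102 CPM in the 2 day 5 pieces. Solyc_MM_06G001022 stood at 0.302 CPM at day 3 (3 counts) and 584 CPM at day 5, a ratio of 1935 (661.8 to 9389). In the other direction, Solyc_MM_09G001822 was at 80.4 CPM at day 3 and 1.58 CPM at day 5, which was 50.8-fold lower (28.2 to 102). Solyc_MM_06G002476 was at 92.8 CPM at day 3, 3.16 CPM at day 5 (29.3-fold lower, 19.2 to 47.0) and 63.5 CPM at day 7. For Solyc_MM_06G002476 the log2 ratio was -3.45 in the parts of the sections with lower x positions and -6.24 in those with higher x positions, against -4.87 over all spots. Across all alternative settings, that of Solyc_MM_09G001822 (-5.67) ran from -6.23 to -4.37. When each day 5 piece was set against the day 3 piece, 345 of the 484 genes and 140 of the 295 were apart in the same direction in both comparisons. Within the outer zone of the tissue alone (set by distance from the edge), the number of lower genes was 178, of which 124 were among the 295.

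From day 5 to day 7, 610 genes were at least 2-fold higher and 447 at least 2-fold lower (525 and 514 with median-of-ratios scaling). Solyc_MM_10G001582 was at 0.719 CPM at day 5 (5 counts) and 81.9 CPM at day 7, a ratio of 114 (48.5 to 352), and it ranged from 13.9 to 139.7 CPM among the 4 day 7 pieces. Solyc_MM_09G002498 was at 1.87 CPM at day 5 and 199 CPM at day 7, which was 106-fold higher (62.1 to 200.5), with 85.8 to 289 CPM in the day 7 pieces. Solyc_MM_06G002228 was at 141 CPM at day 5 and 2.29 CPM at day 7, 61.7-fold lower (38.4 to 106). Solyc_MM_10G001531 was at 267 CPM at day 5 and 4.72 CPM at day 7, 56.5-fold lower (40.5 to 81.4). It was also below its day 5 level at day 3, at 89.9 CPM. In all 8 comparisons of a day 7 piece with a day 5 piece, 87 of the 610 genes and 116 of the 447 were apart in the same direction. The log2 ratio of Solyc_MM_09G002498 was 6.73 over all spots and ran from 5.77 to 7.76 across the alternative settings, and that of Solyc_MM_06G002228 was -5.95 and ran from -8.09 to -5.09. Those of Solyc_MM_10G001582 (6.83) and Solyc_MM_10G001531 (-5.82) ran from 5.12 to 7.82 and from -6.81 to -5.25, where the first had 0 counts at day 5 in the part with lower x positions and no ratio there.

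Between day 3 and day 7, the longest interval, 791 genes were at least 2-fold higher and 560 at least 2-fold lower at day 7. The 2 identifiers with the highest ratios were those that led at day 5. Solyc_MM_10G001532 stood at 464 CPM at day 7, with 59.3 to 849 CPM in the 4 pieces, and Solyc_MM_06G001022 at 353 CPM, with 123 to 636 CPM in the pieces. Solyc_MM_01G004339 was at 91.9 CPM at day 3 and 0.404 CPM at day 7 (3 counts), a ratio of 227 in favour of day 3 with a counting interval of 77.5 to 1104. Solyc_MM_03G002065 was at 59.8 CPM at day 3 and also at 3 counts at day 7, a ratio of 148 (50.4 to 719). Across the alternative settings the log2 ratios of these last 2 models, -7.83 and -7.21, ran from -9.03 to -5.18 and from -8.24 to -5.77. With median-of-ratios scaling the numbers of higher and lower genes were 679 and 711, so the excess of higher genes depended on scaling to total counts. That scaling moved all log2 ratios relative to total-count scaling, with log2 factors of -0.05 at day 3, -0.01 at day 5 and 0.09 at day 7. In all 4 comparisons of a day 7 piece with the day 3 piece, 206 of the 791 genes and 207 of the 560 were apart in the same direction.

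Over the 3 sections, 1941 genes were at least 2-fold apart in at least 1 pair of days. A level at least 2-fold above both other sections was found for 424 genes at day 7, 197 at day 5 and 162 at day 3. A level at least 2-fold below both others was found for 230 genes at day 3, 170 at day 7 and 63 at day 5. At each of the steps from day 3 to day 5 and from day 5 to day 7, 16 genes were at least 2-fold higher and 9 at least 2-fold lower, and these are included in the counts for days 3 and 7 above.

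The pieces of 1 day also differed from each other. By the number of genes apart, this spread was smaller than that between days with 1 exception. By the same rule as for days, the 2 day 5 pieces had 242 genes at least 2-fold apart, and the 6 pairs of day 7 pieces had 358 to 813 (median 479.5). Pieces of days 3 and 5 had 792 and 863 genes apart, pieces of days 5 and 7 had 942 to 1370, and pieces of days 3 and 7 had 1075 to 1733. The exception was the day 7 pair with 813 genes, which lay between the 2 counts for days 3 and 5. Of the 1351 genes apart between days 7 and 3, 600 (44.4%) were also apart in at least 1 of the 6 pairs of day 7 pieces, against 22.0% of all 5243 genes with at least 50 CPM in a section. Of the 779 genes apart between days 5 and 3, 73 (9.37%) were also apart in the 1 pair of day 5 pieces, against 3.80% of the 5243. The 2 percentages of overlap rest on unlike numbers of pairs and are not comparable with each other.

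**Figure D1:**
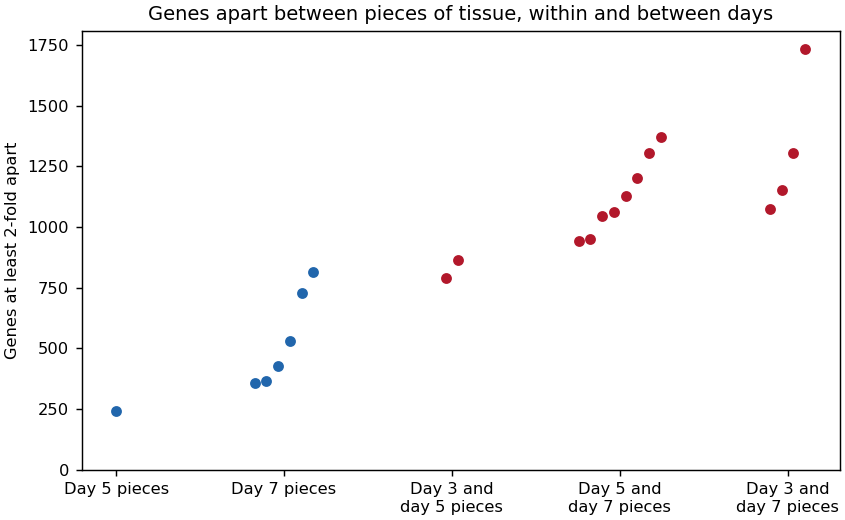
Number of genes at least 2-fold apart (y axis, linear from 0) for each pair of tissue pieces, with pairs of the same day in blue and pairs of different days in red; each point is 1 pair. The day 5 pair had 242 genes apart, day 7 pairs had 358 to 813, and pairs of days 3 and 7 had 1075 to 1733.

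Position within the root tissue separated genes in the same direction at all 3 days. Spots of each piece were divided into 3 zones with equal numbers of spots by distance from the tissue edge, a division chosen after the positions were seen, and the outer and inner zones were compared. Of 3953 genes with a mean of at least 50 CPM, 118 were at least 1.5-fold higher in the outer zone than in the inner zone of all 7 pieces, and 9 were at least 1.5-fold higher in the inner zone of all 7. If pieces were unrelated, 0.00610 and 0.0131 genes would be found in every piece. The log2 ratios of inner over outer zone correlated between pieces across genes with Pearson's r from 0.442 to 0.709 for pieces of different days and 0.534 to 0.753 for pieces of 1 day, where genes are not independent replicates. Solyc_MM_10G001957 was at least 5.45-fold higher in the outer zone of each piece, with 326 CPM there against 33.2 CPM in the inner zone at day 3 and 1379 against 42.7 CPM in day 7 piece 4. Solyc_MM_02G002463 was 4.74-fold to 17.7-fold higher in the outer zone. Solyc_MM_08G001154 was 2.16-fold to 3.05-fold higher in the inner zone, with 96.3 against 34.1 CPM at day 3 and 512 against 174 CPM in day 7 piece 1. Solyc_MM_10G001960 was 1.80-fold to 4.48-fold higher in the inner zone. Inner spots held more counts, with medians 1.74 to 4.17 times those of outer spots. With each piece restricted to spots in its interquartile range of counts, 62 outer genes and 1 inner gene passed 1.5-fold in every piece.

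**Figure D2:**
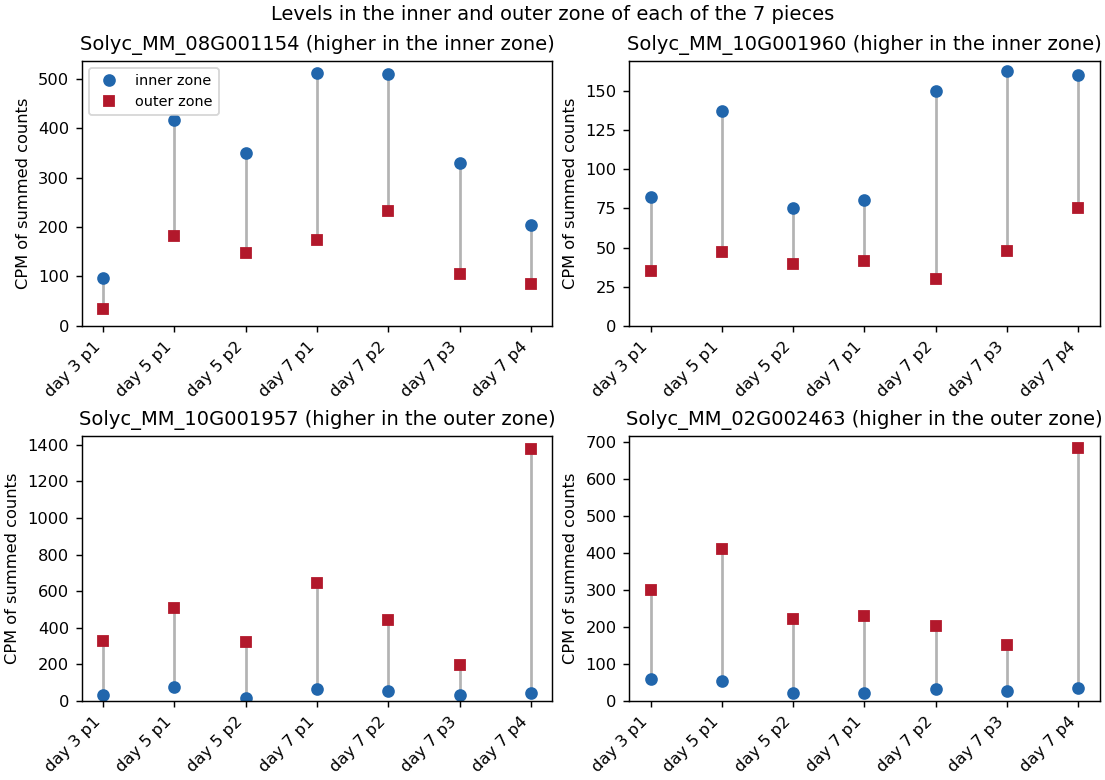
CPM of summed counts (y axes, linear from 0) of 4 gene models in the inner zone (blue circles) and outer zone (red squares) of each of the 7 pieces (x axes, p for piece). In each piece, Solyc_MM_08G001154 and Solyc_MM_10G001960 were higher in the inner zone, and Solyc_MM_10G001957 and Solyc_MM_02G002463 in the outer zone.

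The outer genes had a higher median level at day 7 than at days 3 and 5 over whole sections, but the differences between days depended in size on the zone and piece. Their direction differed between pieces and, from day 3 to day 5, also between zones. From day 3 to day 7, 39 of the 118 were at least 2-fold higher, 25 at least 2-fold lower and 54 neither, with a median log2 ratio of 0.54 that lay above that of all 10000 random lists of the same size and expression (percentile 100). That median was 0.27 in the inner zone alone, 1.03 in the outer zone alone and -0.02 to 0.86 for the 4 day 7 pieces. From day 5 to day 7, 43 were higher and 14 lower, with a median of 0.47 (percentile 100). Among the 8 pairs of pieces of these 2 days, the median ran from -0.43 to 1.34. From day 3 to day 5 the median was -0.23, with -0.58 in the inner zone and 0.20 in the outer zone. The 9 inner genes had medians of 0.10 from day 3 to day 5 and 0.53 from day 3 to day 7 (percentiles 87.7 and 96.5), with 2 of the 9 at least 2-fold higher and 0 lower in both comparisons. Their medians were 0.24 and 0.31 when each day 5 piece was set against day 3, and 0.03 to 0.84 for the 4 day 7 pieces.

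Galls are local swellings, so each piece was also divided into 3 zones by the local thickness of the tissue. Between the thickest (wide) and thinnest (narrow) zones, 11 genes were at least 1.5-fold higher in the wide zone of all 7 pieces and 37 in the narrow zone of all 7. Solyc_MM_08G001154, which was also higher in the inner zone, was 2.18-fold to 35.0-fold higher in the wide zone. Solyc_MM_11G002443 was 1.79-fold to 8.78-fold higher in the wide zone, and its level at the wide zone was 191 CPM at day 3 and 357 and 374 CPM in the day 5 pieces, against 43.7 to 149 CPM in the day 7 pieces. Solyc_MM_08G002491 was 2.35-fold to 7.12-fold higher in the narrow zone. The narrow genes shared 28 members with the 118 outer genes, where 1.10 would be shared by unrelated lists, and the wide genes shared 2 with the inner genes (0.0250). When thickness was compared among spots at a similar distance from the edge, 0 wide and 7 narrow genes passed 1.5-fold in every piece, so thickness was not separated from edge distance for most of these genes. The 11 wide genes had a median log2 ratio of 1.05 from day 3 to day 5 (5 higher, 0 lower) and -0.99 from day 5 to day 7 (0 higher, 4 lower), at percentiles 99.9 and 0.0400 of the random lists. Against day 3 the median was 0.15 and 1.24 in the 2 day 5 pieces, and from day 5 to day 7 it ran from -1.32 to -0.27 over the 8 pairs of pieces. The 37 narrow genes had medians of 0.79 from day 5 to day 7 (16 higher, 3 lower) and 0.61 from day 3 to day 7 (11 higher, 6 lower), both at percentile 100. Over pairs of pieces these ran from -0.34 to 1.55 and from 0.05 to 1.17. The median from day 3 to day 7 was 0.24 in the inner zone alone and 1.25 in the outer zone alone. In day 7 piece 3 the wide over narrow ratios correlated least with those of other pieces (r from 0.143 to 0.309, against 0.364 to 0.706 among the others).

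Clustering each section on its own gave 7 regions at day 3 and 8 each at days 5 and 7, and these were contiguous in space. Of neighbouring spots, 83.7% at day 3, 73.4% at day 5 and 86.5% at day 7 lay in 1 region, against 18.8%, 15.4% and 15.8% for spots placed at random. At day 3, region 1 formed the core of the root, with 25.4% of spots and 83.5% of them in the inner zone. Region 2 lay along the margin, with 63.0% of its spots in the outer zone. Region 4 occupied 1 end of the piece and was labelled by Solyc_MM_08G002387, at 3339 CPM there against 20.4 CPM in the rest of the section. Region 5 occupied the opposite end and had a median of 8594 counts per spot. Region 7 was a group of 15 spots that all lay in the inner zone, labelled by Solyc_MM_09G002735 at 6165 CPM and a log2 ratio of 7.79 over the rest of the section. Regions also differed in depth, with median counts per spot of 6848 in day 3 region 1 and 2248.5 in day 3 region 2. The medians ran from 495 to 3242 at day 5 and from 513.5 to 2260 at day 7. Counts were scaled per spot before clustering, but depth was not otherwise controlled. How far depth shaped the regions was not tested.

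**Figure D3:**
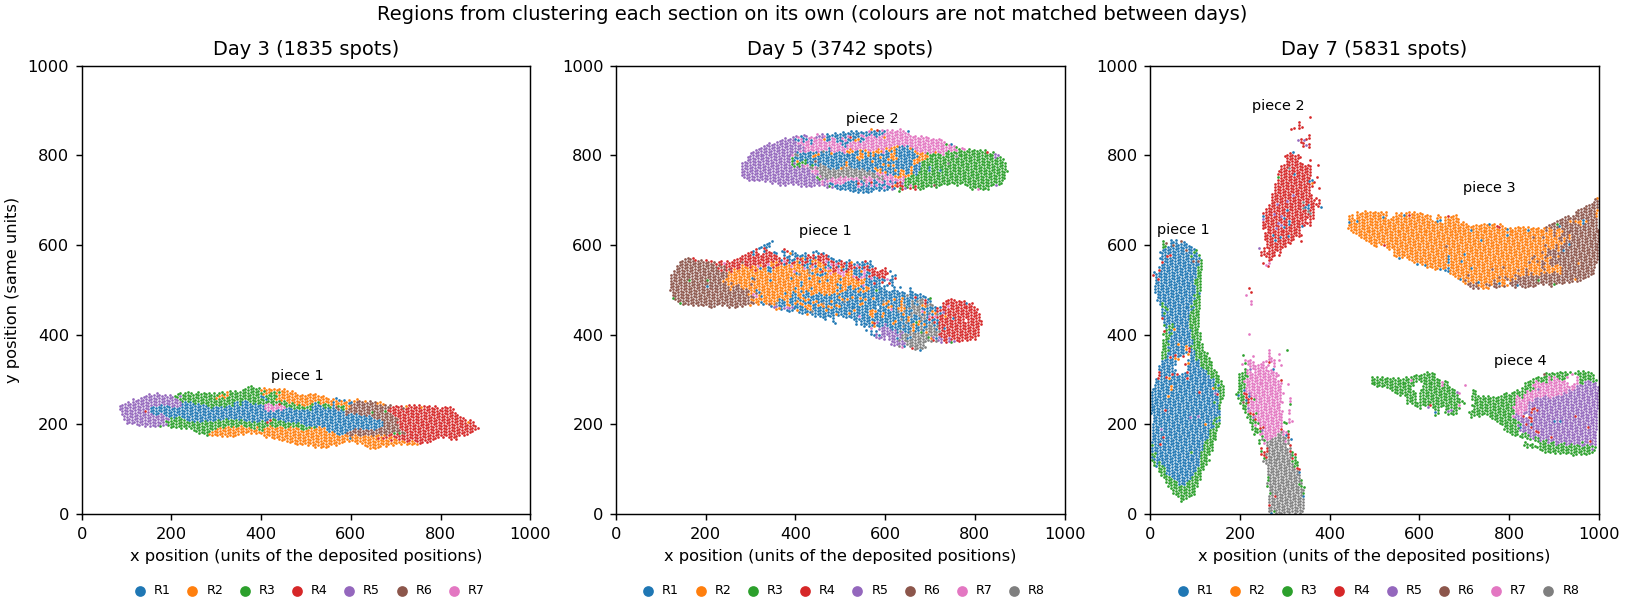
Spots of the day 3, day 5 and day 7 sections at their deposited x and y positions (unit not stated), coloured by region within each section; colours of different days are not matched. Regions formed contiguous cores, rims and ends, with 83.7%, 73.4% and 86.5% of neighbouring spots in 1 region.

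Regions of different days were matched by their gene profiles. Day 3 region 1 and day 5 region 1 were each other's best match among regions, with r = 0.725 across 3953 genes between their log2 ratios against the rest of their section. Day 7 region 5 was the mutual best match of both, with r = 0.450 to day 3 region 1 and 0.504 to day 5 region 1, and 95.5% of its spots came from piece 4. Of day 5 region 1, 50.2% of spots lay in the inner and 26.6% in the outer zone, against 83.5% inner for day 3 region 1. Of day 7 region 5, 60.9% lay in the inner zone. The day 5 region with the highest inner share was region 2 (67.7%, with 8.57% outer), which correlated with day 3 region 1 at r = 0.472 and matched day 7 region 2 mutually (r = 0.307). Among peripheral regions, day 5 region 6 and day 7 region 3 matched mutually (r = 0.615), as did day 3 region 2 and day 5 region 4 (r = 0.477). Day 3 region 4, at 1 end of the piece, had 41.3% of its spots in the outer and 20.6% in the inner zone. It matched both day 5 region 5 (r = 0.453) and day 7 region 3 (r = 0.408) mutually. Day 7 region 3 was a rim found in 3 pieces, with 70.8% of its spots in the outer zone and 183 genes at least 4-fold above the rest of the section, more than in any other region. Day 3 regions 3, 5, 6 and 7 had no mutual best match at a later day. Day 7 regions 1, 2, 4, 5, 6 and 8 took 91.0% to 100% of their spots from 1 piece each, and day 5 regions 3, 4 and 6 took 96.3% to 99.5%, so each may represent that piece and not a tissue type. Region membership depended on the clustering, with adjusted Rand indices against the reported regions of 0.614, 0.661 and 0.723 at days 3, 5 and 7 at resolution 1.0, and 0.868, 0.595 and 0.899 with 30 neighbours. With each region followed to the one that overlapped it most, 3 of the 8 mutual matches remained mutual at resolution 1.0 and 6 with 30 neighbours. The matches among day 3 region 1, day 5 region 1 and day 7 region 5 remained with 30 neighbours but not at resolution 1.0.

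Spatial patchiness was described by Moran's I over the 6 nearest spots after each spot was thinned to 337 counts. Among 1132 genes measurable in all 3 sections, 22 had I of at least 0.1 at day 3, 49 at day 5 and 94 at day 7, and 0 genes did so when spots were shuffled (highest 0.0475). Without thinning the numbers were 614, 585 and 451, in the opposite order. The unthinned counts were scaled per spot and log-transformed, so the order of the days depended on how counts were treated. The part due to depth alone was not tested. The number of pieces also rose over the days, and I was computed over all pieces of a section together. A gene that differed between pieces could therefore gain I at days 5 and 7, which was not tested. With thinning, 16 genes had I of at least 0.1 at all 3 days. Of the 100 genes with the highest I in each section, 58 were shared by days 3 and 5, 64 by days 5 and 7, 50 by days 3 and 7 and 45 by all 3, where 8.83 would be shared by unrelated pairs of lists. Fewer than 100 genes reached 0.1 on each day, so this overlap describes ranks. Of the outer genes, 20, 22 and 23 of the 44 measurable were in the top 100 of the 1132 genes at days 3, 5 and 7. Outer genes were chosen from the same spots for a difference between zones, which can by itself raise I. Solyc_MM_08G002387 had the highest I at day 3 (0.530). Solyc_MM_02G000010 had the highest at day 5 (0.606) and day 7 (0.710), against 0.0537 at day 3, and its level was 332, 2160 and 2365 CPM on the 3 days. Solyc_MM_01G004494 was second at both later days (0.426 and 0.505) and was higher in the inner than in the outer zone in 7 of 7 pieces.

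**Figure D4:**
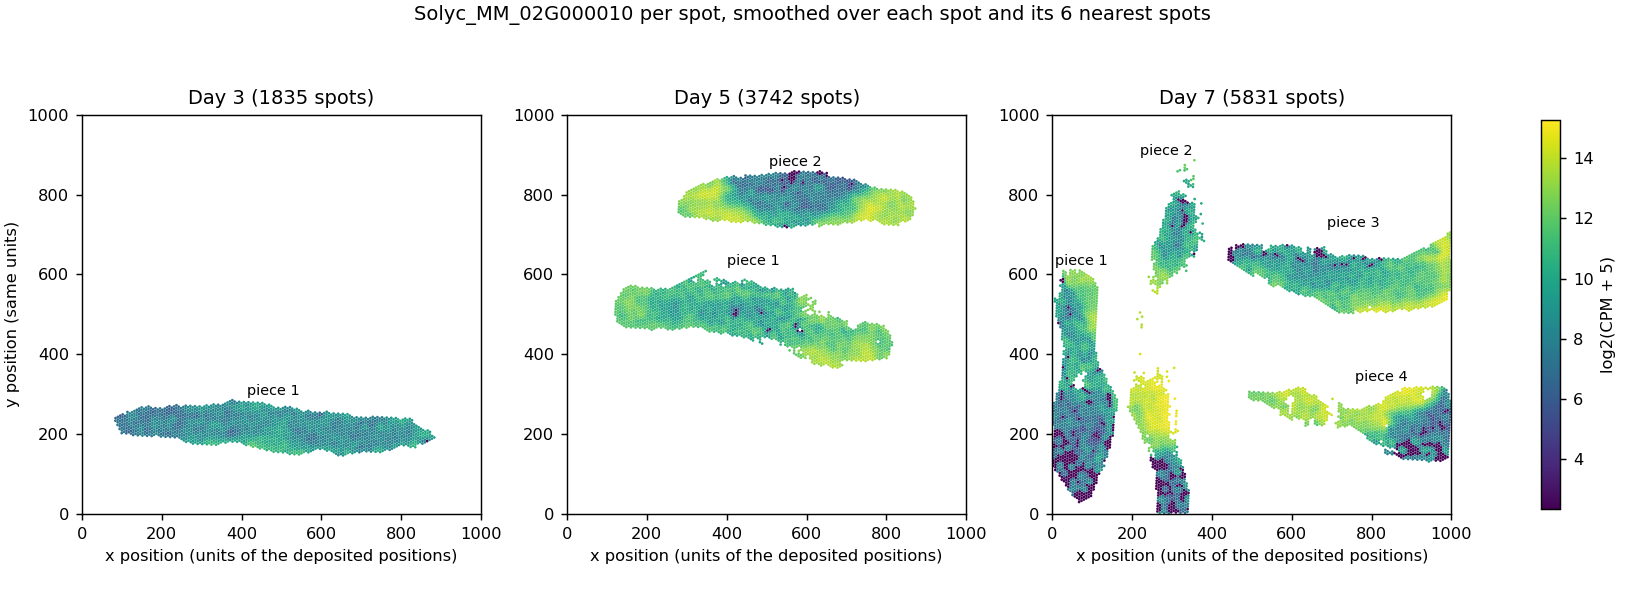
Solyc_MM_02G000010 in each section as log2(CPM + 5) over each spot and its 6 nearest spots (colour), at the deposited x and y positions (unit not stated). The gene model was at 332 CPM overall at day 3, with a Moran's I of 0.0537, and formed bands at the ends of pieces at day 5 (2160 CPM) and in parts of pieces 2, 3 and 4 at day 7 (2365 CPM).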

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

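The division into inner and outer zones was chosen after the positions were seen. The choice of the 3 genes named, the 3 counts of genes with opposite directions and the tests of tissue position and depth follow from it. The bounds of those tests were set before they were computed. The differences between days in direction were not tested, since each day had 1 library.

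The direction between inner and outer zones was opposite between days for a few genes. From day 3 to day 5, 15 genes were at least 1.5-fold higher in the inner zone at day 3 and in the outer zone of both day 5 pieces, and 1 gene went the other way. Solyc_MM_08G002387 had a log2 ratio of inner over outer zone of 1.68 at day 3 and of -1.56 and -1.13 in the day 5 pieces. At day 3 it labelled region 4 at 1 end of the piece. Solyc_MM_05G001978 had -1.42 at day 3 and 0.62 and 0.71 at day 5. Between days 3 and 7, 3 genes were higher in the inner zone at day 3 and in the outer zone of all 4 day 7 pieces, led by Solyc_MM_09G001637 (0.74 at day 3, -2.46 to -0.76 at day 7). Unrelated sections would give 32.6, 11.5 and 20.6 such genes, so reversal was rarer than for unrelated sections.

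More genes were at least 2-fold apart between days 3 and 7 (1351) than between days 3 and 5 (779). Within the outer zone alone, 1311 genes were apart between days 3 and 7, above the bound set for a different mix of inner and outer tissue. Between days 3 and 5, 485 genes were higher and 178 lower at day 5 in that zone. The zone test does not decide, since the outer zone is set relative to each piece and can hold unlike tissue on the 2 days. Pieces reached 8.89 spots from the edge at day 3 and 12.1 to 13 spots at day 7. Over spots with 1000 to 3000 counts, 1268 genes were apart, above the bound set for unequal depth per spot. That test does not decide, since the window can take unlike tissue on the 2 days. Median counts were 2395 in outer and 6708 in inner spots at day 3. In the day 7 pieces they were 409 to 638 in outer and 762 to 2505.5 in inner spots. The days of infection and any other difference between sections or plants cannot be told apart with 1 library per day. The day 3 piece differed from each day 7 piece by at least 1075 genes, against at most 813 between pieces of day 7. Pieces of 1 day share their library, however, and the day 3 piece held more counts, which lets more genes pass the interval.

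The 118 outer genes stood out in every piece, and outer spots held fewer counts. Their median outer over inner log2 ratio was 1.98 over all spots and 1.39 over spots in the interquartile range of counts of each piece, where the ratio of inner to outer depth had dropped from 2.80 to 1.36. Depth may account for part of the ratio, and fewer genes (62) passed 1.5-fold in every piece there. Within the wider zone of each piece the median was 1.48, above the bound set for tissue at the ends of pieces as the source. The 118 genes were chosen over spots that include those of both restrictions, which favours a high ratio there. How far wide spots lay from the ends was not measured, so the test does not decide on the ends as a source. No biological explanation was tested, because the gene models could not be named.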

How the results depend on the processing

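No paired analysis was possible because each day had 1 library and the labels give no replicate numbers. The alternatives on pieces, tissue position, depth windows and region matches were chosen after seeing the data. The median log2 ratio of the outer genes from day 3 to day 5 (-0.23) reversed to 0.20 in the outer zone alone and was -0.58 in the inner zone. Other medians that left their range over pieces were 1.03 (outer genes) and 1.25 (narrow genes) from day 3 to day 7 in the outer zone, and for inner genes from day 3 to day 5 0.0646 with median-of-ratios scaling and 0.17 in the inner zone, where the reported 0.10 also lay below its range. The other 21 of 27 kept to it. Median-of-ratios scaling also turned the balance of higher and lower genes from day 3 to day 7 from 791 and 560 to 679 and 711. Of 104 alternative values for counts of genes, regions and matches, 88 stayed within 1.5 times the reported count. Membership changed more. Of the 295 genes lower at day 5 than at day 3, 42.0% were called again in the outer zone, 52.5% over spots with 1000 to 3000 counts and 67.1% with the mean of CPM per spot. For the other 5 lists of genes between days the lowest share was 58.2% to 75.2%. Of 125 log2 ratios of single genes, 109 stayed within their counting intervals and the others kept their sign, while 7 more had no value because 1 section had 0 counts. These genes were named only if they kept their direction under median-of-ratios scaling and in parts of the sections. Their sign under those alternatives was thus fixed by the choice. Leaving out day 7 piece 2 could not change values for days 3 and 5, which are included among the 104 and the 125. Without the minimum of 50 CPM, the numbers of higher and lower genes were 1618 and 867 for day 5 over day 3, 1715 and 1058 for day 7 over day 5, and 2645 and 1335 for day 7 over day 3, since more genes were admitted. In the outer zone alone, 178 genes were lower at day 5 than at day 3. All other alternatives gave 445 to 529, 466 to 671 and 627 to 930 higher genes for the 3 pairs. Of 8 mutual matches of regions, 3 remained at resolution 1.0. Without thinning, 614, 585 and 451 genes had Moran's I of at least 0.1 at days 3, 5 and 7, the opposite order of days. There all counts of a spot entered, scaled per spot and log-transformed, so depth was not the only change. Inner genes numbered 20 with 4 zones in place of 3 and 1 within the interquartile range of counts, where outer genes numbered 62. Wide and narrow genes numbered 0 and 7 within zones of similar edge distance. The cause was not tested for the counts and medians by zone or for the matches. Keeping listed genes in the clustering changed nothing because none matched, and shifts of gene lists were not run for the same reason. Depth limits the lowest levels, since 3 counts correspond to 0.302, 0.432 and 0.404 CPM at days 3, 5 and 7.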

Other observations

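The tests and values in this part were chosen after the data were seen, with bounds for the 2 tests on the run of gene models set before those tests were computed. At day 3, a few genes had most of their counts in a small focus of the root. Among 10980 genes with at least 100 counts, 10 had at least 50% of them within 1 window of 15 neighbouring spots, and 0 did so after spots were shuffled (highest 17.2%). Solyc_MM_09G002735 had 61.6% of its 1086 counts in a window that held 1.25% of all counts, 7 spots from the edge, at 5398 CPM against 42.5 CPM outside. It was at 3.88 CPM at day 5 and 0.943 CPM at day 7. The other 9 genes shared a second focus farther along the root, 6 to 6.56 spots from the edge, with 50.4% to 61.6% of their counts there. The window had a median of 11377 to 11545 counts per spot, against 4865 in the section. One of the 9, Solyc_MM_05G000824, was at 2874 CPM in the window and 45.2 CPM outside it. It was not lower at the later days (92.1, 221 and 152 CPM at days 3, 5 and 7), but its best window held 8.65% of its counts at day 5 and 9.32% at day 7. At days 5 and 7, 0 genes passed 50%, also with windows enlarged to 31 and 48 spots in proportion to the section. The highest shares in windows of 15 spots were 45.7% and 36.8%, against 44.0% and 35.4% after spots were shuffled. These sections held 2 and 4 pieces, and a gene with a focus in each piece would divide its counts among them. The 50% rule therefore does not show that foci were absent at days 5 and 7. Whether these foci correspond to feeding sites was not tested, since no image or marker was analysed.

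The 10 gene models with consecutive identifiers from Solyc_MM_02G000001 to Solyc_MM_02G000010 moved as a block. Their summed level was 1051 CPM at day 3, 6515 CPM at day 5 and 6247 CPM at day 7, which was 6.20-fold and 5.94-fold above day 3, and 9 and 8 of the 10 were at least 2-fold higher on their own. The level was 2756 CPM in day 7 piece 1 and 7866 to 9352 CPM in the other 3 day 7 pieces, and 6201 and 6630 CPM in the day 5 pieces. These levels are shares of all counts, and median counts per spot were 4865, 1099.5 and 826 at days 3, 5 and 7. Among regions, the block had 3.64 to 11.2 counts per spot at day 3, 5.35 to 36.7 at day 5 and 1.15 to 25.9 at day 7. How much of the rise from day 3 came from fewer other counts was not tested. The next 10 models by identifier summed to 3.42, 5.18 and 5.26 CPM. A second block of 8 models, Solyc_MM_00G000011 to Solyc_MM_00G000018, went from 342 CPM at day 3 to 2194 and 1897 CPM. Within sections the first block formed bands, from 1833 CPM in day 5 region 7 to 23455 CPM in day 5 region 5, and from 891 CPM in day 7 region 8 to 38002 CPM in day 7 region 7. At day 3 it ran only from 673 to 1672 CPM. A lower number of other counts is argued against as the whole cause of the highest bands at days 5 and 7. The block had 4.36 times as many counts per spot in its highest as in its lowest region at day 5 and 22.5 times at day 7. At day 3 the ratio was 0.644, so a lower number of other counts remains open for the smaller differences there. It also remains open for other bands at the later days. Day 5 region 4 had 9040 CPM at 5.35 block counts per spot, against 1833 CPM at 6.08 in day 5 region 7. Day 7 region 3 had 13678 CPM at 8.65 block counts per spot, against 2469 CPM at 7.09 in day 7 region 5. Block members took part in the clustering, so spots were also ranked by the share of the block in their 6 nearest spots, a check added later without a bound of its own. Between the highest and lowest 10% of spots the ratios were 0.813, 6.75 and 27.4 at days 3, 5 and 7. A single source, such as ribosomal RNA from repeated genes, may underlie the block, and would keep its members in 1 ratio. The highest over lowest share of a member among regions had a median of up to 1.64, between the bounds of 1.5 and 2, so the test does not decide. Solyc_MM_02G000010 took 18.8% of the block in day 5 region 7 and 46.9% in day 5 region 4, and no biological explanation was tested.

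A few outer genes had consecutive identifiers. The 118 outer genes included 5 pairs with consecutive identifiers, against a mean of 0.606 in random lists matched on expression, and 4 of 10000 such lists had at least as many. Most outer genes were in no such pair, and other groups of genes were not compared.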
